A study of Danio rerio with 2 samples.

How the data were processed

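RNA from whole zebrafish embryos was measured in 2 libraries, 1 of WT and 1 of ezh2 homozygous mutant embryos at 28 hours post fertilization. Per the labels' protocols, RNA was extracted with Trizol, poly(A) RNA was isolated and libraries were made with the NEBNext Ultra RNA kit, a kit that does not mark strand. How many embryos went into each library is not given in the sources used here. The submitters' processing notes name the genome build GRCz10, Bowtie 0.12.2 and Cufflinks, without saying what each was used for; the counting tool and the test behind the FDR are not given in the sources used here. Reads from a gene and from an overlapping antisense gene therefore cannot be told apart, and reads of near-identical copies may have been divided between them.

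Each library's column was matched to its sample by the code in the sample title. Per the file headers, the authors deposited for each gene a raw read count and an FPKM per library, and an FDR and a log2 fold change of mutant over WT. The counts are whole numbers with no normalization, and the FPKM values are scaled by the authors for transcript length and library size. The FDR, a p-value adjusted by the authors, and the log2 fold change come from the authors' own comparison of 1 library with 1 library, so they compare those libraries and not the genotypes. Tested on the file, each of the 1287 genes has an FDR of at most 0.00996 and an absolute log2 fold change of at least 1 in the authors' deposited table, and 58 have an FDR listed as 0. The table is therefore a selection: the library totals are unknown, nothing can be said about genes outside it, and no enrichment was computed.

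The authors' log2 fold change lay within 0.1 of the log2 ratio of the counts with 2 added, on a constant scale, for 96.3% of genes. That scale, the median difference between the authors' log2 fold change and the log2 count ratio over 391 genes with at least 200 counts in both libraries, was 0.0144 (a factor of 1.01 for the mutant library), and it was used for each fold here. The log2 fold change of a gene was log2((mutant count + 0.5)/(WT count + 0.5)) plus that scale. Folds printed as "-fold" are ratios of counts on the same scale, with a 95% exact (Clopper-Pearson) interval that treats the counts as independent draws. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The 25 genes with 0 WT counts have a lower bound, computed against a floor of 3 counts in that library, which leaves out the error of the mutant count; no listed gene had 0 mutant counts, and no member of a gene list had 0 counts.

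The table has no column of gene symbols. Symbols were taken from the zebrafish KEGG hit that the table gives (562 genes), updated by gene ID in the supplied RefSeq table of assembly GRCz12tu, which was used for names alone; 77 genes were named from the product or Swiss-Prot name in the table, and hits that contradicted the product name were dropped. In this way 579 of the 1287 genes received a symbol, 5 of them clone-style, and 1110 have a symbol or a descriptive product name; 20 are newly assembled loci. A KEGG hit can be the closest paralogue, so genes that share a symbol are reported as uncertain. A gene list member that the table holds under a product name that was not recognised would be missed. No coordinates are given, since no annotation of the authors' build was used here.

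The 41 gene lists, the fold, the alternatives and the rule for named genes were fixed before the data were examined, apart from a change to that rule given below. In all, 152 listed genes belong to at least 1 list. For the 15 lists with at least 3 listed members, the median log2 fold change was set against 10000 random lists of the same size, matched member by member on 10 bins of mean count, among the 1287 genes; the percentile is the percent of random lists with a median at or below that of the list, and describes these libraries alone. The counting interval of a median comes from 10000 Poisson redraws of its members' counts. The rule for named genes also covered ezh2 and the other PRC2 members, but none of them was listed. All 96 named genes therefore come from 3 further groups. The first was the 10 largest rises and 10 largest falls among genes with a descriptive name and at least 50 counts in one library. The second was up to 4 members of each list with the largest absolute fold at that floor. The third was the 5 most abundant genes with a descriptive name at least 2-fold higher and the 5 at least 2-fold lower. The fixed rule asked for a descriptive symbol. Since the table has no symbols, a product name was also counted as a descriptive name, a choice made after the table was opened. Results for some of these genes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

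The steps were tested on simulated data made for the comparison of the mutant with the WT library. Independent Poisson counts of the 1287 genes were drawn with 200 genes changed, 100 by 2-fold and 100 by 4-fold. All simulated genes were kept, without a selection by fold or FDR. The draws share the interval's own assumption, so they check the computation and not how it performs on selected genes. The exact interval held the true fold for 95% of the genes changed 2-fold, 99% of those changed 4-fold and 96.1% of the 1087 unchanged genes. The interval of the median held the true median for 92% of 200 lists of 11 genes, a little less often than its nominal 95%. A planted list of 15 raised genes reached percentile 100, and 8% of 200 random lists of 15 genes fell under the 5th or over the 95th percentile.

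Alternatives were other scales (the median, or the 30% trimmed mean, of the log2 folds of the listed genes set to 0, and the implied scale without the 50 most abundant genes), a constant of 5, no constant, the authors' deposited log2 fold change, a minimum of 50 counts in the higher library, a 4-fold threshold and an FDR limit 10 times as strict. Folds from FPKM with 0.1 added were tried after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plot matplotlib 3.10.9.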

Results

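Messenger RNA was profiled in whole zebrafish embryos (Danio rerio, AB background) collected 28 hours after fertilization, from wild-type (WT) embryos and from embryos homozygous mutant for ezh2. Ezh2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine K27 (H3K27me3). Each genotype was represented by 1 library, so the difference between them has no replicate check, and no p-value or spread between replicates can be given. The deposited table holds 1287 genes that the authors had selected as different between the libraries, each with its read count and FPKM in both. Counts in the table ran from 0 to 29755 in the WT library and from 1 to 29568 in the mutant library, with medians of 122 and 196. Their sums, 799647 and 764775, cover the selected genes alone and are not the depth of the libraries. The deposited count per unit of FPKM in the mutant library was 0.978 times that in the WT library (median of 391 well-counted genes), a measure of the relative depth behind the authors' FPKM. Intervals in brackets below are 95% exact intervals of a ratio of counts and cover counting error only. Log2 fold changes given below as from FPKM have 0.1 added to each FPKM value, which shrinks the folds of genes with low FPKM.

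The first question was the level of ezh2 itself in each library. Neither ezh2 nor any other of the 15 fixed PRC2 core and cofactor genes was among the listed genes, so ezh2 was not analysed here and the genotype labels could not be checked on the targeted gene. Of 28 genes of the partner complex PRC1, 4 were listed. The chromodomain gene cbx7a was 15-fold higher in the mutant library (11.4 to 20.7), with 49 WT and 736 mutant counts. The other 3 were lower: cbx6b by 2.43-fold (2.09 to 2.83), cbx2 by 2.09-fold (1.87 to 2.35) and rybpa by 2.04-fold (1.77 to 2.37). The median log2 fold change of the 4 was -1.05 (counting interval -1.17 to -0.91), at percentile 16.5 of 10000 random lists of the same size matched on mean count. None of the 16 trithorax and H3K27 demethylase genes was listed.

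The second question was how many genes differed and in which direction. At least 2-fold higher in the mutant library were 876 of the 1287 listed genes (68.1%), and 411 were at least 2-fold lower. These numbers equal the authors' own calls and are nearly fixed by their selection, since in the authors' deposited table each absolute log2 fold change is at least 1 and the largest FDR is 0.00996. The higher genes started from low counts, with a median of 64 in the WT library, and the lower genes from a median of 492. The median log2 fold change was 1.61 among the higher genes and -1.32 among the lower ones. At 4-fold, 290 genes were higher and 59 lower. The split depends on the scale between the libraries. Centring that scale on the listed genes changes the split by construction, since most of them were selected as higher. With their median log2 fold set to 0, a shift of -1.31 for every gene, 210 genes were at least 2-fold higher (33.8%) and 411 lower. With their 30% trimmed mean set to 0, a shift of -1.22, 225 were higher (35.4%) and 411 lower. Both centred scales lie far from the relative depth behind the FPKM, a factor of 0.978, which also comes from the authors' processing. All folds below are on the scale that the authors' fold changes imply.

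The listed members of a fixed list of cell cycle arrest and damage response genes were higher in the mutant library. All 11 listed members of the 29 fixed cell cycle inhibitor and damage response genes were higher, also under both other scales, and their median log2 fold change was 2.38 (2.25 to 2.48), above that of each matched random list. cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, had 61 WT and 1337 mutant counts, a 22.1-fold difference (17.1 to 29.1). The pro-apoptotic gene bbc3 (Puma) was 17.2-fold higher (12.9 to 23.4), gadd45aa 14.8-fold (11.1 to 20.2) and phlda3 6.54-fold (5.32 to 8.10). ccng1, which encodes cyclin G1, was among the most abundant listed genes, with 10450 WT and 29568 mutant counts, a 2.86-fold difference (2.79 to 2.92). Singled out after its values were seen, mdm2, which encodes a ubiquitin ligase, was 5.20-fold higher (4.83 to 5.61). Related genes not matched to the list, also singled out after their values were seen, went both ways. Lower were ddit4, ccng2, a growth arrest and DNA damage 45 gamma like gene and a mediator of DNA damage checkpoint protein 1-like gene. Higher were gadd45ga, a cyclin-dependent kinase inhibitor 2A-like gene and a 40S ribosomal protein S27-like gene. By name, the inhibitor gene may be the fixed gene cdkn2a/b and the ribosomal gene the fixed gene rps27l.

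Immediate-early and stress genes of the fixed list, where listed, were higher as well. All 13 listed loci matched to the 43 heat shock and stress genes were higher, a pair of them matched to hsp70.1. Their median log2 fold change was 2.42 (2.2 to 2.58), above that of each matched random list. Under both other scales 11 of the 13 stayed higher, and ddit3 and serpinh1b turned lower. The AP-1 transcription factor gene fosab had 43 WT and 1159 mutant counts, a 27.2-fold difference (20.1 to 37.8), and fosl1a was 20.1-fold higher (14.2 to 29.2). A pair of loci whose closest named match is hsp70.1 were 26.3-fold (6.91 to 223) and 11.5-fold (7.21 to 19.5) higher, the first from 2 WT counts (log2 fold change of 4.41, against 3.04 with 5 counts added and 2.84 from FPKM). These chaperone genes belong to a family of similar copies, so the division of reads between them is uncertain.

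The listed members of the fixed immune list and of the fixed matrix list were higher on the authors' scale. Other immune and matrix genes in the table went both ways. For example, lyz and col9a1b below were lower, while interferon gamma receptor 1 and col7a1, chosen after their values were seen, were higher. All 11 listed members of the 49 innate immunity, complement and interferon genes were higher, with a median log2 fold change of 1.37 (1.23 to 1.59) at percentile 79.4 of matched random lists. The log2 folds of c3a.1, c7a, cfb, nfkbiaa and stat3 lie under the shift of both other scales, which left 6 of 11 higher there. The complement gene c3a.2 was 12.3-fold higher (8.36 to 18.8), irf1b 6.67-fold (4.15 to 11.3), the chemokine gene cxcl18b 4.98-fold (2.78 to 9.58) and irf9 3.49-fold (2.86 to 4.28). The more abundant C3 gene c3a.1 had 6136 WT and 14050 mutant counts, a 2.31-fold difference (2.24 to 2.38), and shares sequence with the other C3 copies. Of 30 extracellular matrix and protease genes, 6 were listed and 6 were higher, with a median of 1.66 (1.54 to 1.92) at percentile 93.4; adamts1 turned lower with the median of the listed genes set to 0. Among them adamts9 was 7.65-fold higher (3.46 to 19.9; log2 fold change of 2.85, against 1.82 from FPKM), mmp9 6.03-fold (4.67 to 7.88), the protease inhibitor gene timp2b 3.75-fold (3.19 to 4.42) and mmp13a 2.68-fold (1.97 to 3.69).

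Red blood cell genes of the fixed list, where listed, were lower in the mutant library. All 14 listed loci matched to the 31 erythroid and globin genes were lower. Their median log2 fold change was -1.78 (-1.82 to -1.72), below that of each matched random list. Of these genes, hbae1 and hbbe1.1 were each matched by a pair of loci. The interval and the random lists treat near-identical globin copies, which may share reads, as separate members. An embryonic alpha-globin locus hbae1 (gene4866) had 6838 WT and 684 mutant counts, 9.90-fold lower (9.15 to 10.7). The embryonic beta-globin loci hbbe1.1 were 6.19-fold lower (gene4865, 5.92 to 6.48) and 4.2-fold lower (gene4867, 4.06 to 4.34). hbae3, the most abundant of the globins with 26298 WT and 7693 mutant counts, was 3.38-fold lower (3.30 to 3.47), and hbbe3 was 3.42-fold lower (3.30 to 3.55). Embryonic globin copies are nearly identical, so single loci are uncertain; summed over the 7 listed loci, each selected as lower and without any copy that is not listed, counts were 83689 in the WT and 20454 in the mutant library, 4.05-fold lower (3.99 to 4.11). gata1a, which encodes the erythroid transcription factor Gata1, was 4.84-fold lower (3.39 to 7.10).

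Other blood lineages were listed with fewer genes. All 5 listed of 19 haematopoietic stem and progenitor genes were lower, with a median of -1.28 (-1.58 to -1.08) at percentile 3.84. Among them tal1 was 3.45-fold lower (2.82 to 4.24), myb 3.25-fold (1.97 to 5.58), lmo2 2.43-fold (1.91 to 3.11) and hoxa9a 2.24-fold (1.84 to 2.74); hoxa9a and the other member, hoxa9b, also stand in the trunk and posterior hox list below. Of 26 myeloid, neutrophil and macrophage genes, 6 were listed, 4 lower and 2 higher, with a median of -1.25 (-1.41 to -1.09) at percentile 1.85. spi1a, a paralogue of the myeloid regulator Pu.1, was 4.79-fold lower (2.54 to 9.79) and the lysozyme gene lyz 2.48-fold lower (2.17 to 2.84). The 2 higher members were mmp9 and mmp13a, which also stand in the matrix list above. No member of the lymphoid or endothelium and vessel lists was listed.

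In the neural progenitor list, each listed gene was lower in the mutant library. All 18 listed members of the 36 fixed genes were lower, with a median log2 fold change of -1.48 (-1.55 to -1.38), below that of each matched random list; the random lists had a median of -1.01. The largest differences were in hairy-related (her) genes, transcriptional repressors that act downstream of Notch. her4.3 was 7.98-fold lower (5.97 to 10.9), her4.2 7.29-fold (5.99 to 8.94), her12 4.93-fold (4.21 to 5.81) and her15.2 3.62-fold (3.01 to 4.36). The her4 genes are tandem copies, so single copies are uncertain. Summed over the 5 listed copies, each selected as lower and without any copy that is not listed, counts were 2454 in the WT and 406 in the mutant library, 5.98-fold lower (5.39 to 6.66). The Notch ligand genes dld and dla were 2.91-fold (2.71 to 3.12) and 2.44-fold (2.32 to 2.57) lower. The neuronal gene elavl3, the 1 listed member of 38 differentiated neuron genes, had 13461 WT and 6399 mutant counts, 2.08-fold lower (2.02 to 2.15).

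Glial and retinal genes of the fixed lists were also lower where listed. All 4 listed of 15 glia and myelin genes were lower, with a median of -1.88 (-2.07 to -1.65) at percentile 0.11. olig2, which marks motor neuron and oligodendrocyte precursors, was 4.25-fold lower (3.57 to 5.08), plp1a 3.96-fold (3.69 to 4.25), mpz 3.47-fold (2.48 to 4.92) and olig4 2.26-fold (1.97 to 2.60). Of 31 retina and photoreceptor genes, 2 were listed: atoh7, a retinal ganglion cell determinant, was 4.03-fold lower (2.22 to 7.83) and vsx1 2.76-fold lower (2.07 to 3.72). Outside that list and chosen after its values were seen, a guanylyl cyclase-activating protein 1-like gene, of a family that acts in photoreceptors, was higher.

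Developmental regulators of the kind often marked by H3K27me3 were lower in 22 of 23 listed cases matched by symbol, out of 125 fixed genes. Their median log2 fold change was -1.24 (-1.38 to -1.17) at percentile 0.03 of matched random lists. Genes not matched by symbol are left out of these values. Among them, a single-minded homolog 2 gene (gene3394) and an iroquois-class IRX-5 gene, both lower, may by name be the fixed genes sim2 and irx5a. The homeobox gene gsx1 was 3.56-fold lower (3.01 to 4.22), foxf2a 3.30-fold (2.53 to 4.36) and dbx1a 3.24-fold (2.85 to 3.69). The 1 higher member was gata4, an endoderm and heart regulator, at 3.99-fold (2.38 to 6.99) with 19 WT and 75 mutant counts. The listed members of both hox lists were lower. The 5 listed of 20 anterior hox genes had a median of -1.05 (-1.16 to -0.99) at percentile 32.1, with hoxb2a 2.25-fold lower (1.94 to 2.62), hoxa4a 2.11-fold (1.95 to 2.28), hoxb4a 2.08-fold (1.78 to 2.43) and hoxb3a 2.07-fold (1.92 to 2.23). The 9 listed of 31 trunk and posterior hox genes had a median of -1.17 (-1.33 to -1.09) at percentile 3.97, with hoxc13b 3.08-fold lower (1.99 to 4.89), hoxd12a 2.90-fold (2.11 to 4.03), hoxb10a 2.56-fold (2.11 to 3.11) and hoxa10b 2.27-fold (1.84 to 2.81).

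Mesenchymal and signalling genes were listed in smaller numbers. All 4 listed of 25 sclerotome, cartilage and fin fold genes were lower, with a median of -1.16 (-1.28 to -1.05) at percentile 10.5: prrx1b by 2.45-fold (2.12 to 2.85), sox9b by 2.24-fold (2.07 to 2.43), twist3 by 2.24-fold (1.82 to 2.76) and twist1a by 2.08-fold (1.82 to 2.38). Of 58 Wnt, BMP, hedgehog, FGF and Notch ligand and feedback genes, 7 were listed, 4 lower and 3 higher. Their median was -1.19 (-1.24 to -1.05), at percentile 7.40. The authors' selection left out folds near 0. The median of these 7 is therefore the value of dlb, the least changed of the 4 lower genes, and shows no shared decrease. The lower ones were the Notch ligand genes dla, dlb and dld, which also stand in the neural progenitor list above, and jag1a, 2.36-fold lower (2.06 to 2.71); wnt3a was 2.57-fold higher (2.13 to 3.10), and ihha, also higher, turned lower under both other scales.

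**Figure D1:**
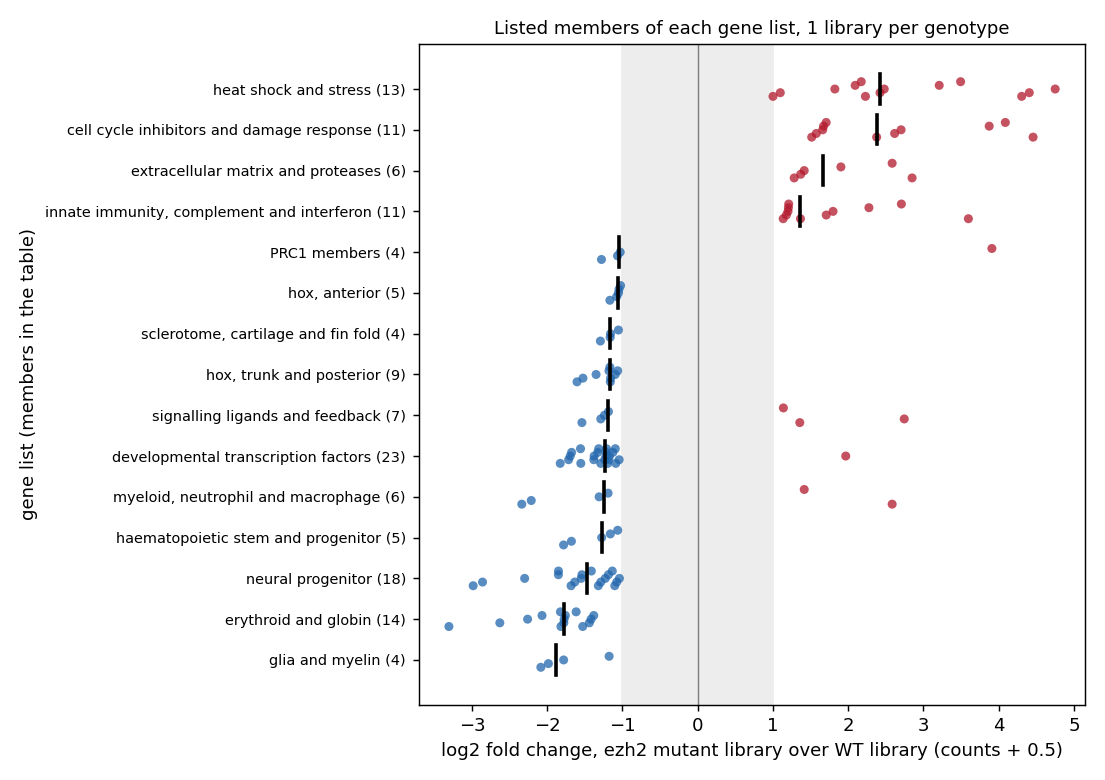
Each point is a listed gene, placed by its log2 fold change (mutant library over WT library, x axis) in the row of its gene list (y axis, number of listed members in brackets), for the 15 lists with at least 3 listed members; red points were higher and blue points lower in the mutant library, black bars are medians, and the grey band is the range that the authors' selection left out. The 13 stress and 11 cell cycle inhibitor and damage response genes lie to the right and the 14 erythroid and 18 neural progenitor genes to the left; with the median of the listed genes set to 0, points shift left by 1.31, and ddit3, serpinh1b, adamts1, ihha and 5 immune genes turn lower.

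Among single genes with a descriptive name and at least 50 counts in one library, the largest differences upward in the mutant library included 3 genes with no WT counts. A cathepsin L1-like gene (gene22783) had 137 mutant counts, at least 46.1-fold higher against a floor of 3 WT counts that leaves out the error of the mutant count; the exact interval, which includes it, starts at 37.0. ADP-ribosylation factor 4b had 90 mutant counts (at least 30.3-fold against that floor, exact interval from 24.1) and a membrane-spanning 4-domains gene, member 17A.4, had 82 (at least 27.6-fold against that floor, exact interval from 22.0); with 5 counts added, which gives no bound, their log2 fold changes were 4.84, 4.26 and 4.14. A gene named tumor necrosis factor receptor superfamily member 27 had 28 WT and 992 mutant counts, 35.8-fold higher (24.6 to 54.1), and a gene named sialic acid-binding Ig-like lectin 12 was 19.7-fold higher (7.39 to 74.1; log2 fold change of 4.14, against 3.22 with 5 counts added and 3.48 from FPKM). The largest differences downward were in prkacbb, a protein kinase A catalytic subunit gene, with 145 WT and 2 mutant counts (71.8-fold lower, 19.5 to 598; log2 fold change of -5.85, against -4.41 with 5 counts added and -3.63 from FPKM), and in a phosphodiesterase 9A-like gene (gene14366) with 67 WT counts and 1 mutant count (66.3-fold lower, 11.5 to 2659; log2 fold change of -5.48, against -3.57 with 5 counts added, -3.60 from FPKM and -4.66 in the authors' deposited values). A gene named immunoglobulin superfamily DCC subclass member 3-like was 12.2-fold lower (8.11 to 19.1; log2 fold change of -3.58, against -2.88 from FPKM), an annexin A2-A-like gene 8.29-fold (3.98 to 20.0), a hairy-related 4.1-like gene 7.63-fold (5.40 to 11.1) and a single-minded homolog 2 gene (gene3394) 6.93-fold (4.32 to 11.7). Among the most abundant genes, a second cathepsin L1-like gene (gene22781) was 2.05-fold higher (2.01 to 2.1), myh9a, a non-muscle myosin heavy chain gene, 2.41-fold (2.34 to 2.48) and mvp, the major vault protein gene, 2.2-fold (2.13 to 2.27). With the median of the listed genes set to 0, gene22781, myh9a, mvp and c3a.1 turned lower. The abundant progenitor gene sox11b was 2.2-fold lower (2.13 to 2.28).

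The remaining lists had at most 2 listed members. Both listed members of the 37 glycolysis and hypoxia genes were lower, ankrd37 by 4.84-fold (3.81 to 6.22) and egln3 by 3.55-fold (2.96 to 4.27). Related genes not matched to that list, chosen after their values were seen, went both ways. Higher were epas1b and an endothelial PAS domain-containing protein 1 gene (gene22989). Lower was a hypoxia-inducible factor 1, alpha subunit, like 2 gene (gene33723). Both notochord and floor plate genes were lower, foxa by 2.16-fold (1.73 to 2.7) and col9a1b by 2.01-fold (1.93 to 2.1), as were both pronephros genes, lhx1a by 2.13-fold (1.81 to 2.52) and mecom by 2.03-fold (1.81 to 2.28). In the neural crest and pigment list tfap2b was 2.03-fold lower (1.69 to 2.45) and xdh 2.1-fold higher (1.69 to 2.62). Among clock and light genes, rorca was 2.44-fold higher (2.05 to 2.92), cry-dash 2.1-fold higher (1.76 to 2.51) and nfil3-2 2.17-fold lower (1.81 to 2.62), while aanat2 was higher and lonrf1 lower, each from under 50 counts in both libraries. With the median of the listed genes set to 0, xdh, rorca and cry-dash turned lower. Single listed members were higher in 5 further lists: smyhc3, a slow myosin gene, by 14.3-fold (5.87 to 45.5; log2 fold change of 3.71, against 2.94 with 5 counts added and 2.12 from FPKM), the lens crystallin gene cryba1a by 4.87-fold (2.51 to 10.3), gata4 of the heart list as above, hmgcra of sterol synthesis by 2.83-fold (1.84 to 4.45) and the epidermal gene anxa1b by 2.55-fold (2.36 to 2.75). No member was matched by symbol for core clock repressors, hatching gland, yolk syncytial layer and lipoprotein, endoderm and its organs, germ cells, cell proliferation, cytosolic ribosomal proteins or mitochondrial genome transcripts. Among genes not matched to the lists and chosen after their values were seen, hatching enzyme 2 (gene34779) was higher in the mutant library. So was a 40S ribosomal protein S27-like gene (gene39452), which by its name may be rps27l of the damage response list. Also higher were the cathepsin L1-like genes gene22781 and gene22783, given above, and gene31663. By name they may be cathepsin L genes of the hatching gland or yolk lists. An actin, alpha cardiac muscle 1 gene (gene31314) was lower, and a fast skeletal muscle myosin heavy chain gene (gene34178) was higher. A gene that is not listed may have differed by less than the authors' thresholds or been left out for another reason, so its level is not known here.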

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

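The FPKM alternative was chosen only after the data were seen. With a constant of 5, no constant, the authors' deposited log2 fold change, a minimum of 50 counts or the scale without the 50 most abundant genes, each of the 15 medians stayed inside its counting interval, with a largest shift of 0.07. What moves the values is a scale centred on the listed genes. Since 876 of the 1287 were selected as higher, such a scale subtracts 1.31 (median) or 1.22 (trimmed mean) from each log2 fold by construction. The 11 list medians below 0 and the 411 lower genes cannot turn under it, and the 4 list medians above 0 stayed above 0. It left 210 or 225 genes at least 2-fold higher, and 411 lower in both cases. A 4-fold threshold left 290 higher and 59 lower. The other settings stayed within 1.5 times of the main counts.

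List medians with the median of the listed genes set to 0, then with the trimmed mean set to 0, were -2.35 and -2.27 for PRC1, -3.08 and -3.00 for erythroid and globin genes, -2.58 and -2.50 for haematopoietic stem and progenitor genes, -2.56 and -2.47 for myeloid genes, -2.47 and -2.38 for sclerotome, cartilage and fin fold, -2.78 and -2.70 for neural progenitors, -3.19 and -3.11 for glia and myelin, -2.36 and -2.28 for anterior hox genes, -2.47 and -2.39 for trunk and posterior hox genes, -2.54 and -2.46 for developmental transcription factors, -2.49 and -2.41 for signalling ligands, 1.07 and 1.15 for cell cycle inhibitor and damage response genes, 1.12 and 1.2 for heat shock and stress, 0.059 and 0.14 for innate immunity, and 0.35 and 0.44 for matrix and proteases. With FPKM plus 0.1 in place of counts, 3 medians left their counting interval: erythroid and globin genes (-1.82), glia and myelin (-1.56) and cell cycle inhibitor and damage response genes (2.48). The cause was not tested.

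Of the 96 named genes, 7 turned lower with the median set to 0, c3a.1 (-0.10), gene22781 (-0.27), cry-dash (-0.24), mvp (-0.17), myh9a (-0.038), rorca (-0.021) and xdh (-0.24), and 5 of them with the trimmed mean set to 0, c3a.1 (-0.014), gene22781 (-0.19), cry-dash (-0.16), mvp (-0.085) and xdh (-0.16). These turns restate that the log2 fold of the gene lies under the shift. Under the other alternatives run on single genes, each named gene that gave a value kept its direction, but not always its size. With 0.1 added to FPKM, 15 of the 96 left their counting interval, and the largest shift from the main log2 fold change was 2.22. With a constant of 5, 3 left it, and the largest shift was 3.28. These 3 were the genes with no WT counts (gene22783, ADP-ribosylation factor 4b and member 17A.4). With 0.1 added to FPKM, the log2 fold change was -3.63 for prkacbb, -3.60 for gene14366 and 2.12 for smyhc3. It was 2.84 for the hsp70.1 locus with 2 WT counts and 1.82 for adamts9. That constant is large beside the lower FPKM of these genes, such as 0.0404 for prkacbb in the mutant library, so it shrinks their folds. Depth limits the genes with few counts: 25 genes had 0 and 48 had 1 to 3 WT counts, and their folds rest on the constant or on a lower bound. Centring on the listed genes assumes as many rises as falls among genes chosen by the authors. The relative depth behind the FPKM (a factor of 0.978) lies close to the scale that the authors' folds imply and far from both centred scales; both values come from the authors' processing, and without the genes that are not listed a difference in RNA composition could not be checked. No paired analysis was possible because each genotype has 1 library.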

Other observations

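Further gene families were grouped by name after their values were seen, some of which share members with the fixed lists, and their directions are on the authors' scale. All 10 listed desmosomal and plakin-family genes, such as dspa, ppl and evpla, were higher in the mutant library, with a median log2 fold change of 1.24; summed counts were 10845 in the WT and 23643 in the mutant library. With the median of the listed genes set to 0, 3 of the 10 stayed higher, and with the trimmed mean set to 0, 6 did. All 3 listed laminin genes were higher (median 2.12), as were all 5 listed caspase genes (median 1.57), of which 4 stayed higher with the median set to 0. A fibronectin gene (gene94) had 1221 WT and 11371 mutant counts, 9.41-fold higher (8.87 to 9.99). By its name it may be fn1a or fn1b of the fixed matrix list, but it was not matched by symbol and is not in that list's values.

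On the lower side, all 16 listed genes of the her, hes and hey families were lower, with a median of -1.85 and 3.25-fold lower summed counts (3.14 to 3.37). All 7 listed POU genes (median -1.48), all 6 SOX genes (median -1.15) and all 6 linker histone and HMGB genes (median -1.10), among them h1f0 and hmgb1a, were lower too. Of 49 listed genes whose product name holds homeobox or a like word, 48 were lower. In the eukaryotic orthologous group classes that the table gives, 26 of 117 transcription genes were higher (22.2%), against 48 of 55 genes of protein modification, turnover and chaperones (87.3%) and 68.1% of the listed genes together. Genes are not replicates, so these shares describe the table alone.

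The test on summed globin counts below was chosen only after the values were seen; the other tests were fixed before list values were computed, although single globin genes and six6b had been seen. Lower erythroid and globin values: reads divided differently between near-identical globin copies stay open for the globin loci. The sum over 7 loci was 4.05-fold lower (3.99 to 4.11), but each of the 7 was selected as at least 2-fold lower and copies that are not listed are missing from the sum, so it decides nothing. Fewer blood cells of every lineage stay open too. The share of listed myeloid genes that were higher was 33.3%, under the 50% fixed for that explanation. The 2 higher ones, mmp9 and mmp13a, also belong to the matrix list. This share rests on 6 listed of 26 fixed myeloid genes, each selected as changed, so it cannot decide on every lineage. Lower transcript levels per cell stay open as well, and lymphoid genes were not listed.

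Lower neural progenitor values: a younger stage of the mutant embryos stays open. The test fixed for it was the share of higher genes among the 18 listed progenitor genes, which was 0%, but this restates the pattern and decides nothing, and no other stage was measured. A lower share of neural tissue in the mutant embryos could not be judged, since 1 differentiated neuron gene was listed and 5 were needed. Loss of neural cells is therefore untested here.

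Developmental transcription factors: a hypothesis from the known role of Ezh2 was that loss of repression at genes often marked by H3K27me3 would place more of them among the higher genes than the 68.1% of the whole table. Of the 23 listed, 4.35% were higher, so the prediction was not met, which argues against a rise as the main direction at the listed genes. H3K27me3 was not measured here, so whether these genes carried the mark in these embryos is unknown. In whole embryos a small number of cells with regained expression may be hidden by lower expression where the gene is normally active, and genes that moved by less than the authors' thresholds are not listed.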
